A study of Mus musculus with 10 samples.

How the data were processed

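Polyadenylated RNA was sequenced from CD4 T cells sorted by flow cytometry from C57/BL6 mice 35 days after intranasal immunization with heat-killed Klebsiella pneumoniae, per the labels. The labels list 10 libraries in 5 populations. Draining lymph node (LN) cells were naive (2 libraries) or memory (2 libraries), and lung tissue-resident memory (TRM) cells were Th17 (1 library), exTh17 (3 libraries) or YFPneg (2 libraries). Lymph nodes were passed through a cell strainer, whereas lungs were digested with collagenase and separated on a Percoll gradient, per the labels' protocols, so organ and tissue preparation cannot be told apart. Libraries were made with an Illumina TruSeq mRNA kit, per the labels' protocols. Strand handling during counting was not given in the sources used here.

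The deposited expression table held FPKM values (fragments per kilobase of transcript, scaled to the mapped fragments), 1 per population, computed by the authors. The header names no unit, and FPKM was taken from the values and from Cufflinks in the submitters' processing notes. CASAVA 1.8, FastQC, TopHat2, Bowtie2 and Cufflinks are named there without further versions, with the builds mm10 and GRCm38. How the libraries of a population were combined was not given in the sources used here. The other deposited file was the authors' GRCm38 gene annotation, whose coordinates (unit: first and last base) gave the gene positions.

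Only population values were used here, so no value has a standard deviation or a number of replicates. The tests fixed before the data were examined (limma and camera on separate libraries) could not be run on these values, nor could leaving out a library. They were replaced by a rule of size, chosen once the table's form was known. The difference between 2 populations was taken on the log2(FPKM + 1) scale, which understates differences of weakly expressed genes. A gene was compared if it had a value above 0 in both populations and at least 1 FPKM in at least 1 of them, and it was counted as differing at 2-fold or more. A gene listed at 0 in 1 population received no fold and was counted apart, because an exact 0 in such a table can be a failed estimate.

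The table held 56857 rows, of which 18363 had no gene name and 445 named more than 1 protein-coding gene. Rows naming exactly 1 protein-coding gene numbered 22488, and the row with the highest mean was kept for each of 21587 genes. Of the kept rows, 438 also named a non-coding gene, and 772 genes had more than 1 row. Unnamed rows took 23.5% of the FPKM sum in YFPneg and 36.4% in exTh17, with LN naive, Th17 and LN memory between. Depth was not given; the FPKM worth of 1 fragment in a 2 kb transcript, estimated from the lowest values, was 0.0116 in LN naive, 0.00708 in LN memory, 0.0254 in Th17, 0.0064 in exTh17 and 0.0102 in YFPneg. The Th17 column was therefore the shallowest, while depth per library was not estimated.

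Gene lists were fixed before the data were examined: 25 lists with 371 distinct genes, of which 355 had a row of their own, 13 shared a row with other genes and 3 had no matching row. They covered TRM genes higher and lower in resident cells, naive and recirculation genes, Th17, Th1, Th2, Treg, Tfh and cytotoxic genes, cytokine survival signals, chemokine receptors, inhibitory receptors, lipid use, glycolysis, immediate early and stress genes, proliferation, interferon response, CD4 T-cell identity, and markers of CD8, NK and gamma-delta cells, B cells, macrophages and dendritic cells, neutrophils, lung epithelium, endothelium and stroma, and erythroid cells. A list's median log2 difference was placed as a percentile among 10000 random lists of the same size, matched on mean expression in 20 bins, which describes these columns and is not a test of the populations.

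The genes named in each comparison followed a rule fixed before the data were examined. They were the 8 highest and 8 lowest differences past the size rule with at least 5 FPKM in the higher population, up to 4 members of each list described, members going against their list, and a set of anchor genes. Gene models without a standard symbol and receptor segments were left out. With no p-values, list members were taken by the size of the difference, and the condition on separate libraries was dropped. Genes outside the rule are said to be so where they appear, and some genes the rule names, and a further pattern whose tests were taken out of the tables, are not reported here.

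The comparison code was tested on simulated columns. For exTh17 against LN memory, 9905 simulated genes carried 50 genes each at log2 differences of 1.5, 2, 3 and -2, with noise of 0.2 (SD, log2) per column. The rule found 92% of the genes at 1.5 and 100% at 2, at 3 and at -2, and called 0.0103% of the 9705 unchanged genes. The noise of 0.2 was chosen, not measured. It lay below the 0.36 taken from the spread between exTh17 and YFPneg, real differences included. These shares therefore check the code and are not error rates of the real columns. Unchanged populations sharing the LN memory column were simulated 100 times over 9636 genes, with the same noise for every gene. Its SD was the scaled median absolute deviation of the differences between exTh17 and YFPneg divided by the square root of 2, real differences included. Alternatives were another pseudocount, no filter, median-of-ratios scaling and, added after seeing the data, a 4-fold rule, every row of the table, summed rows and a minimum of 10 FPKM. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.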

Results

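CD4 T cells from the draining lymph node and the lung of immunized mice were profiled by RNA sequencing, and 1 FPKM value was given for each of 5 populations. The labels name 10 libraries, namely 2 of LN naive, 2 of LN memory, 1 of lung Th17, 3 of lung exTh17 and 2 of lung YFPneg cells. At 1 FPKM or more, 8508 protein-coding genes were found in LN naive, 9292 in LN memory, 8860 in Th17, 9360 in exTh17 and 9317 in YFPneg cells. Because each value is the authors' value for the population, no difference has a replicate check, and all counts below describe these columns. CD4 T-cell identity was even across them: Cd4 ranged from 132 FPKM in YFPneg to 191 in exTh17, and Cd3e from 260 in Th17 to 504 in exTh17.

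The closest pair of populations was exTh17 and YFPneg, with a Spearman's correlation of 0.944 across genes. It was 0.902 between Th17 and exTh17 and also between LN naive and LN memory, 0.881 between Th17 and YFPneg, 0.862 between LN memory and YFPneg, 0.842 between LN memory and exTh17 and 0.723 between LN naive and Th17, over genes that are not independent replicates. Of 10766 genes, 2449 were higher in every lung population than in both lymph node populations and 2108 were lower in every one, or 22.7% and 19.6%, where 10% would fall in each class if the columns had no structure. Differences of at least 2-fold against both nodes were seen for 689 genes higher in lung and 173 lower.

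The comparison of exTh17 with LN memory cells addresses what distinguishes resident cells of Th17 origin from memory cells of the node. Genes of tissue residency were higher in exTh17 cells. Cxcr6, a chemokine receptor of lung-resident T cells, was 1862 against 120 FPKM, a log2 difference of 3.95. The regulator of G-protein signalling Rgs2 was 619 against 30.4, Vps37b was 395 against 11.9, and the co-inhibitory receptor Ctla4 was 362 against 13.7. Dapl1, a gene of naive T cells, was lower at 0.918 against 169.

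Of 9905 genes compared, 1365 were at least 2-fold higher in exTh17 cells and 1161 lower, 478 and 195 at 4-fold. In the TRM list, 19 of 29 compared genes were higher and 1 was lower, with a median log2 difference of 1.88 at percentile 100 of random lists. The gene against the list was Xcl1, with a log2 difference of -3.45. Without Nr4a1 and Nr4a2, the members that are also on the immediate early list, 27 genes gave a median of 1.67 at percentile 100. Taking out only these genes cannot separate residency from an effect of tissue preparation. Of 17 genes known to be lower in resident cells, 9 were lower and 2 higher (median -1.07, percentile 0), with Eomes at -2.54 and Tcf7 at -2.07, whereas Cx3cr1 (1.8) and Ly6c2 (1.27) went the other way. Naive and recirculation genes were lower for 12 of 20 and higher for 1, Satb1 (median -1.33, percentile 0). S1pr1 and Klf2, which direct exit from tissue, differed by only 0.38 and 0.18, Ccr7 by -0.95 and Cd69 by 0.44. Itgae was 8.56 against 2.01 FPKM, and Il7r 329 against 195.

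Th17 genes were higher for 17 of 22 and lower for 2, Blk and Il21 (median 2.10, percentile 100). Il17a was 109 against 0.0929 FPKM and Il17f 313 against 1.60. The receptor gene Il23r was 14.6 against 0.827, in a row that also names the gene model Gm4761, and Ltb4r1 59.7 against 0.522. Ccr6 was 127 against 47.8. Th1 genes were higher for 8 of 17 and lower for 1, Ccl5 (median 0.95, percentile 99.98), with Ifng at 31.7 against 11.5 and Tbx21 at 6.74 against 3.02. Th2 genes were higher for 4 of 6 and lower for 2 (percentile 99.99), with Ccr8 at 257 against 17.4, Areg at 12.5 against 0.0386 and Il4 at 0.183 against 47.3. Gata3 was listed only in a row joined with another gene, at 37.5 against 34.7. Treg genes were mixed, 6 higher and 4 lower of 16, with Folr4 at 2.37 against 593 and Foxp3 at 0.954 against 2.01. Genes of follicular helper cells, several of which B cells also express, were lower for 12 of 14 and higher for 2 (median -2.44, percentile 0), with Slamf6 at -3.53 and Cd200 at -3.43, and the higher members were Icos and Pdcd1.

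Signals of cytokine survival were higher for 10 of 15 genes and lower for 0 (median 2.12, percentile 100), with the STAT-induced genes Cish at 103 against 5.78 FPKM and Socs3 at 40 against 2.91. Chemokine receptors were higher for 11 of 20 and lower for 2, and inhibitory receptors higher for 5 of 10 and lower for 3. Lipid genes were higher for 7 of 16 (median 0.81, percentile 99.87), with the lipid droplet gene Plin2 at 112 against 7.20 and Fabp4 at 17.1 against 0.995, but Plin2, Fabp4 and Pparg are also macrophage genes. Glycolysis genes were higher for 3 of 16 (percentile 96.96), led by Hk2. Cytotoxic genes were higher for 6 of 13 and lower for 2 (percentile 85.83). Proliferation genes were lower for 10 of 18 and interferon response genes for 6 of 12, with Birc5 at -3.27 and Usp18 at -2.33.

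Immediate early genes, which tissue digestion also induces, were higher in exTh17 cells for 18 of 24 and lower for 3 (median 1.96, percentile 100). Fos was 231 against 3.87 FPKM and Junb 512 against 8.45. Macrophage and dendritic markers were higher for 12 of 18 and lower for 1, Flt3 (median 2.54), with Chi3l3 at 477 against 0.753 and Lyz2, chosen after its values were seen, at 3543 against 131. B-cell markers were lower for 10 of 10 (median -2.49), with Cd79b at 88.4 against 718. Erythroid genes were lower for 4 of 5, and neutrophil genes higher for 3 of 3. Lung epithelial genes were higher for 4 of 5, with Scgb1a1 of airway club cells at 3189 against 0.547, and endothelial and stromal genes higher or lower for 0 of 3. CD4 T-cell identity genes were higher for 1 of 12 and lower for 1, Cd3d. Among the largest differences, Ccl6, Cd14 and Il1b are macrophage genes, and Crem and Lmna were 1628 and 419 FPKM in exTh17. On the lower side Rgs13, Art2b and Pdzk1ip1 differed by -4.83, -4.65 and -4.39. Rabggtb and Cd27 had small RNA genes inside their span, 3 and 1.

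**Figure D1:**
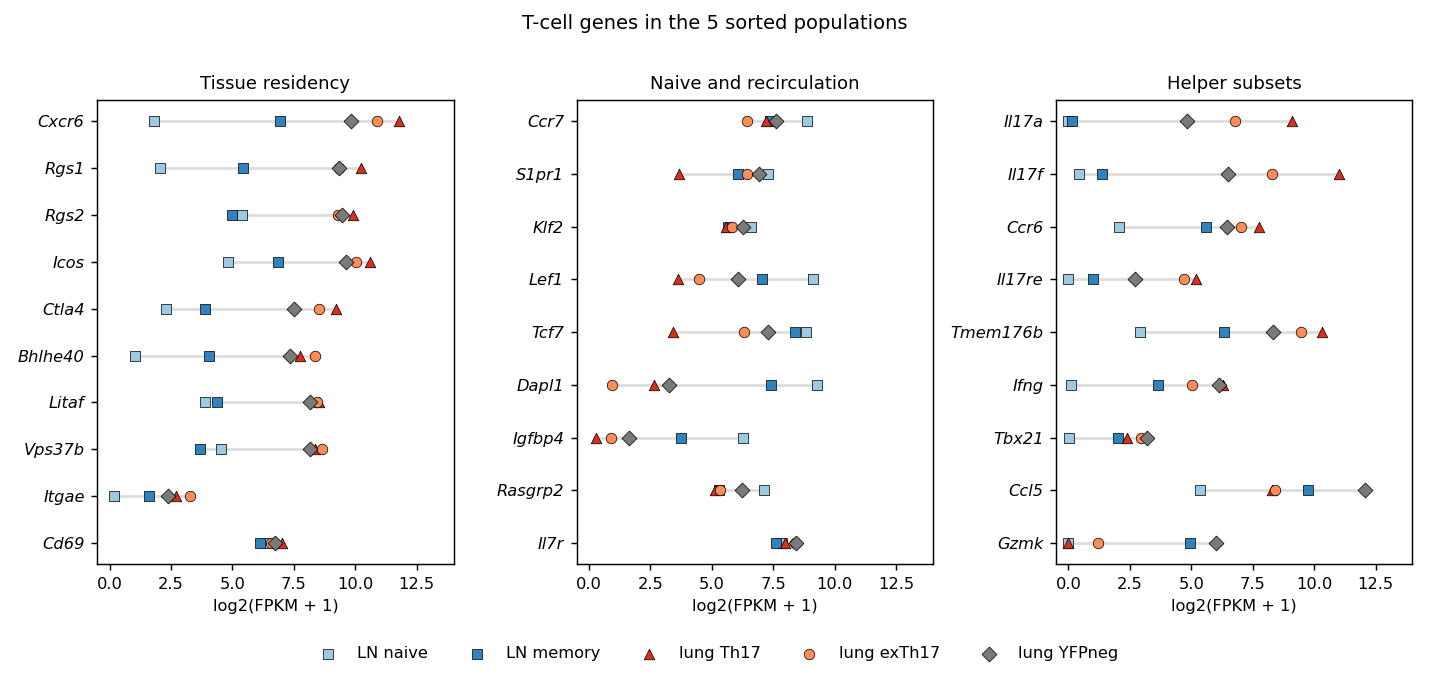
Each symbol is the authors' value for a population on a log2(FPKM + 1) axis for 28 T-cell genes, squares for lymph node and other shapes for lung populations. Cxcr6 ran from 2.55 FPKM in LN naive to 3467 in Th17, while Cd69 and Il7r hardly separated the populations, and no error bars exist because each population has 1 value.

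Genes known to be higher in resident cells were also higher in YFPneg lung cells than in LN memory, whereas genes known to be lower in resident cells were mixed. Cxcr6 was 903 against 120 FPKM, Rgs1 645 against 41.5, Icos 779 against 114, and Gzmb, encoding a cytotoxic protease, 103 against 1.17. Ccl5, a chemokine of effector T cells, was 4343 against 871, and Ifng 69.7 against 11.5. Dapl1 was lower at 8.58 against 169.

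Of 9876 genes compared, 1250 were at least 2-fold higher in YFPneg cells and 1082 lower, 413 and 116 at 4-fold. The TRM list was higher for 21 of 29 and lower for 0 (median 1.8, percentile 100). Genes lower in resident cells were lower for 6 of 17 and higher for 3, Cx3cr1, Klrg1 and Ly6c2, with a median of -0.59 and a mean of -0.01. Naive genes were lower for 9 of 20 and higher for 2, Ccr9 and Satb1. Th17 genes were higher for 16 of 23 and lower for 1, Il21 (median 1.62, percentile 100), with Il17a at 27.3 against 0.0929 and Il17f at 90.0 against 1.60. Th1 genes were higher for 12 of 17 and lower for 1 (median 1.58, percentile 100), with Il12rb2 at 14.6 against 1.09. Cytotoxic genes were higher for 11 of 14 and lower for 0 (median 2.20, percentile 100), with Gzma at 103 against 4.92, and markers of CD8, NK and gamma-delta cells were higher for 2 of 5 and lower for 1, Ncr1 (percentile 97.27), with Klre1 at 11.5 against 0.0195. Tfh genes were lower for 11 of 14 and higher for 2, Icos and Pdcd1, with Bcl6 at 1.83 against 12.9. Treg genes were higher for 9 of 17 and lower for 4, cytokine survival genes higher for 9 of 15, inhibitory receptors for 7 of 10, with Havcr2 at 9.77 against 0.108 and with Lag3 and Btla lower, and Th2 genes for 4 of 6, with Il4 lower.

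S1pr1 was 121 against 65.9 FPKM, Ccr7 193 against 166, Klf2 75.5 against 49.5, Il7r 345 against 195, Cd69 106 against 69.6 and Itgae 4.18 against 2.01. Immediate early genes were higher for 15 of 23 and lower for 2, with Fos at 213 against 3.87. Macrophage markers were higher for 11 of 18 and lower for 2 (median 1.92), with Lyz2 at 4141 against 131, and B-cell markers lower for 9 of 10 (median -1.78). Proliferation genes were lower for 6 of 19, and erythroid genes for 5 of 5. The largest differences included Ccl6, Chi3l3, Cd14, Il1b, Ear2 and Ccl9, all known from macrophages, with Crem and Calca, which encodes a neuropeptide precursor, at 76.4 against 0.0951. Gcsam, Cxcl13 and Clu were lowest besides Rabggtb and Raver1, which hold 3 and 1 small RNA genes. Values of Chi3l3, Ear2 and Ccl6 are uncertain because near-identical relatives can share fragments.

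The exTh17 and YFPneg differences from LN memory overlapped. Of 9636 genes compared in both, 942 were higher in both, where independent lists would share 154.8, and 550 were lower in both, where 125.0 would be shared. Only 5 genes passed in opposite directions. The correlation across genes was 0.854, with a covariance of 0.984. Both comparisons use the same LN memory values. Simulated unchanged populations that share this column gave 18.2 genes higher in both and 21.8 lower in both, a correlation of 0.5 and a covariance of 0.0940, at a noise of 0.36 (SD, log2) per column taken from the spread between exTh17 and YFPneg. The noise of LN memory itself is not known from 1 value, which cannot be split, so part of the excess may come from the shared column. With LN naive as the reference for YFPneg, 720 were higher in both (179.1 for independent lists), 329 lower in both (110.2), and 144 opposite.

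**Figure D2:**
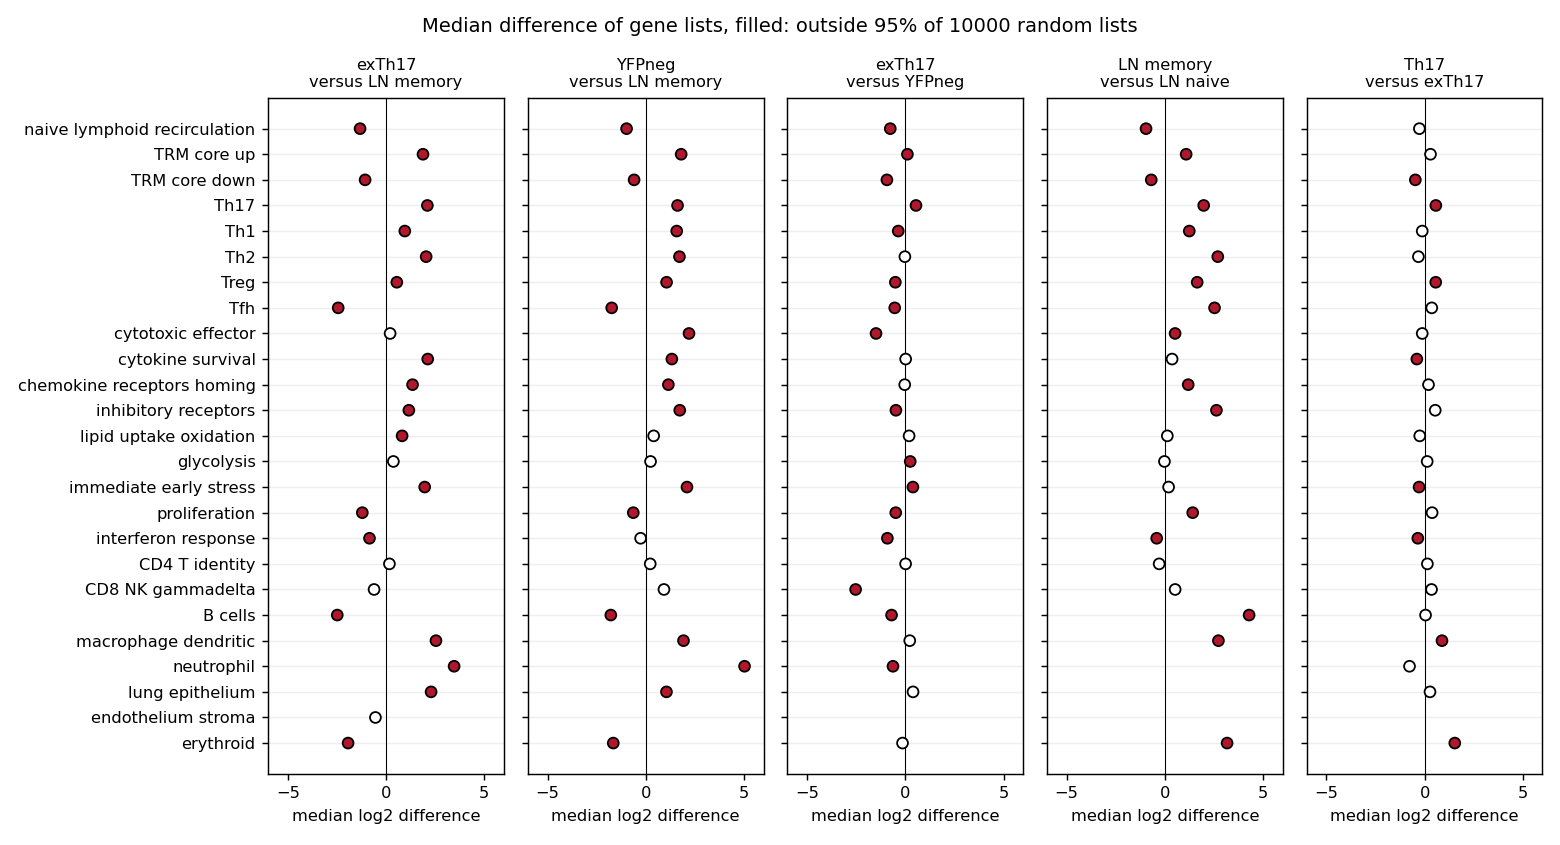
Each circle is a gene list's median log2 difference in a comparison, filled where it lies outside 95% of 10000 random lists matched on expression, for lists with at least 3 compared genes. The TRM list lay at 1.88 and 1.8 against LN memory and the B-cell list at 4.28 in LN memory against naive.

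The comparison of exTh17 with YFPneg cells asks how the lung populations differ from each other. Cytotoxic genes were lower in exTh17 cells, as were markers of CD8, NK and gamma-delta cells, and several Th17 genes were higher. Whether such other cells in the YFPneg sort contribute to the cytotoxic difference was not tested. Ccl5 was 335 against 4343 FPKM, a log2 difference of -3.69, Gzmk 1.28 against 62.5, Gzmb 18.4 against 103 and Nkg7 284 against 1061. Il17a was 109 against 27.3, Il17f 313 against 90.0, and Il17re, a receptor subunit gene of the IL-17 family, 25.3 against 5.48.

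Of 9789 genes compared, 450 were at least 2-fold higher in exTh17 and 440 lower, 23 and 54 at 4-fold. Cytotoxic genes were lower for 8 of 14 and higher for 0 (median -1.49, percentile 0). Th17 genes were higher for 9 of 24 and lower for 2 (median 0.54, percentile 100), with Il23r at 14.6 against 5.01, Ltb4r1 at 59.7 against 15.6 and Ccr6 at 127 against 87.2. Th1 genes were lower for 4 of 17, among them Ifng at 31.7 against 69.7, while Tbx21 was 6.74 against 8.06. Treg genes were lower for 3 of 14 and higher for 1, Il2ra, with Folr4 at 2.37 against 98.3, and Tfh genes were lower for 4 of 14 and higher for 1, Bcl6. The TRM list held 3 higher and 3 lower of 29 (median 0.10, percentile 98.02, mean -0.07), with Cxcr6 at 1862 against 903 and Xcl1 at 5.07 against 73.8. Naive genes were lower for 7 of 19 and genes lower in resident cells for 7 of 16, with Klrg1 at 2.70 against 16.6, Lef1 at 21.6 against 65.9 and Ccr7 at 85.7 against 193.

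Markers of CD8, NK and gamma-delta cells were lower for 4 of 5 (median -2.53), with Cd8b1 at 4.73 against 50.7 FPKM. Proliferation genes were lower for 6 of 19 and interferon response genes for 5 of 11. Immediate early genes were higher for 5 of 24 and lower for 1, Dusp2, with Junb at 512 against 146. Macrophage markers passed in 0 of 20, B-cell markers in 0 of 9, and CD4 T-cell identity genes in 0 of 12. Lung epithelial genes were higher for 3 of 7 and lower for 0 (percentile 93.88), with Scgb1a1 at 3189 against 53.5 and Scgb3a2 at 18.1 against 1.14. Cyp2f2 at 45.0 against 0.0477, Cbr2 at 21.1 against 0.965, Pcbd2, Cpe and Rcn2 were also among the highest, and Klra9, Sostdc1 and Cd7 among the lowest. Sbno1 at 929 against 11.5 and Cstf2 at 6.06 against 257 each hold 1 small RNA gene, as does Cd27. With a pseudocount of 0.1, 1614 genes differed in place of 890.

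The LN memory population differed from the LN naive population in chemokine receptor, naive-cell and B-cell genes. Cxcr6 was 120 against 2.55 FPKM, Cxcr3, a chemokine receptor of Th1 cells, 96.2 against 1.78, Ccr4 51.6 against 0.216, and Tigit, an inhibitory receptor, 88.6 against 1.54. S100a4 and S100a6 were 117 against 0.581 and 256 against 1.84. Naive-cell genes were lower, with Lef1 at 129 against 557 and Igfbp4 at 12.5 against 76.7.

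Of 9307 genes compared, 1061 were at least 2-fold higher in memory cells and 469 lower, 298 and 37 at 4-fold, and 288 further genes at 1 FPKM or more in memory were listed at 0 in naive. At 10 FPKM or more in both, the median log2 ratio was -0.10. Naive genes were lower for 9 of 20 and higher for 0 (median -0.96, percentile 0), including S1pr1 at 65.9 against 155 and Ccr7 at 166 against 466. Tfh genes were higher for 10 of 13 (median 2.52, percentile 100), with Cxcr5, also a B-cell gene, at 75.1 against 4.19, Treg genes for 11 of 16, inhibitory receptors for 7 of 9, Th1 genes for 9 of 17, with Txk lower, and Th17 genes for 9 of 14, with Ccr6 at 47.8 against 3.12. Il17a and Il23r were listed at 0 in naive cells. The TRM list was higher for 14 of 26 and lower for 1, and proliferation genes higher for 13 of 16, with Birc5 at 42.1 against 1.27. Chemokine receptors were higher for 11 of 20 and lower for 2, and cytotoxic genes higher for 4 of 10 and lower for 2, with Prf1, encoding perforin, at 2.51 against 32.2.

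B-cell markers were higher in LN memory for 10 of 10 (median 4.28, percentile 100), with Cd79b at 718 against 21.4 FPKM and Ms4a1 at 178 against 5.07. Whether B cells in the LN memory sort contribute to these values was not tested. The same holds for genes lower in the lung populations than in LN memory. Macrophage and dendritic markers were higher for 7 of 8 and lower for 1, with Cd74, whose span holds 1 small RNA gene, at 7364 against 376, and erythroid genes higher for 4 of 4. Mzb1, Plac8, Napsa, BC028528 and Tnfrsf13c were among the highest, of which Mzb1 and Tnfrsf13c are known B-lineage genes. Among the lowest were Pdlim4, Nacc2, Nme4, Akr1c12, BC024978, and Sbno1 and Ampd1 with 1 small RNA gene each. Cd4 was 189 against 172 and Cd3e 371 against 474.

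**Figure D3:**
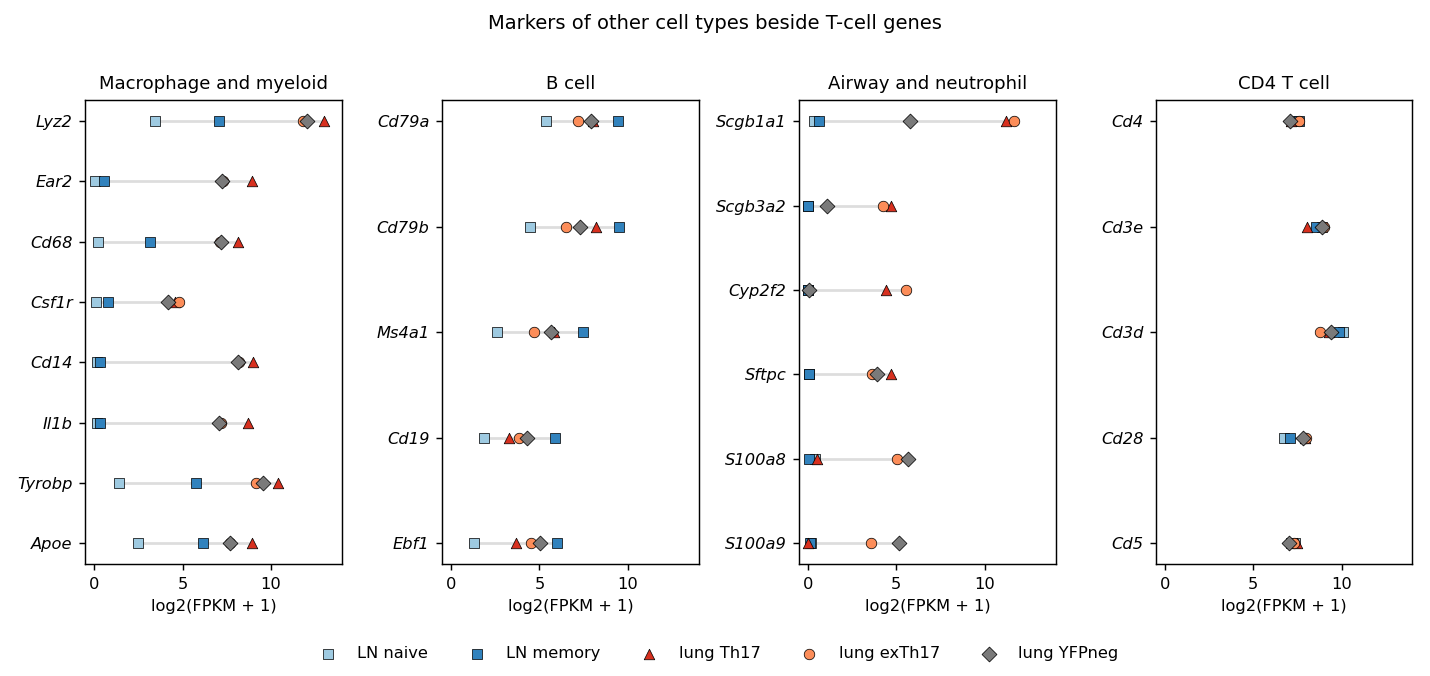
Each symbol is the authors' value for a population on a log2(FPKM + 1) axis for markers of other cell types beside 5 CD4 T-cell genes, with no error bars because each population has 1 value; Cd14, Il1b, Tyrobp, Apoe and Cyp2f2 were added after values were seen. Lyz2 ran from 9.99 FPKM in LN naive to 8286 in Th17, and Cd79a from 40.7 in LN naive to 701 in LN memory.

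The Th17 population, sequenced as 1 library, was set against exTh17 cells. Il17a was higher in Th17 cells at 546 against 109 FPKM, Il17f at 2065 against 313 and the chemokine gene Ccl20 at 31.3 against 5.18, whereas Il22, chosen after its values were seen, was 16.3 against 17.4. Tcf7 was lower at 9.77 against 78.6, S1pr1, needed for exit from tissue, at 11.7 against 86.2, and Cxcr3 at 47.5 against 300.

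At 10 FPKM or more in both, Th17 values were shifted by a median log2 ratio of 0.21. Of 9636 genes compared, 1098 were at least 2-fold higher in Th17 and 1040 lower, 150 and 116 at 4-fold, and 188 further genes at 1 FPKM or more in exTh17 were listed at 0 in the shallower Th17 column. Th17 genes were higher for 6 of 24 and lower for 1 (median 0.57, percentile 98.86), of which 0.21 is the shift, with Ccr6 at 217 against 127, Il23r at 7.55 against 14.6 and Il10 at 7.97 against 0.996. TRM genes were higher for 4 of 29 and lower for 1 (percentile 66.34), with Gzmb at 98.3 against 18.4. Genes lower in resident cells were lower for 6 of 17 and higher for 2 (percentile 0.71). Cytokine survival genes were lower for 4 of 15, with Socs1 at 5.44 against 28.4. Cytotoxic genes were higher for 5 of 13 and lower for 4, and Ifng was 76.4 against 31.7. Cd69 was 128 against 94.5, Itgae 5.60 against 8.56 and Il7r 250 against 329.

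Macrophage markers were higher in Th17 for 8 of 19 (median 0.89, percentile 99.99), with Ear2 at 478 against 158 FPKM, and erythroid genes for 5 of 5. Prmt2 at 2009 against 8.58 and Chpf2 at 167 against 9.25 each hold 1 small RNA gene, as does Fxyd4. Lcn2, Cxcl9, Upp1, Neil2, Car7 and Fam212a were also among the highest in Th17. S100a8, Nudt1, Pabpn1, Dgka, Mettl16, Lyrm5 and Fxyd4 were among the lowest in Th17. Actb and Ubb, chosen after their values were seen, were listed at 0 in exTh17 cells.

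The gene positions in the authors' GRCm38 annotation place Il17a on chromosome 1 at 20730905 to 20734496, Il17f on chromosome 1 at 20777151 to 20784270, Cxcr6 on chromosome 9 at 123806477 to 123811754 and Scgb1a1 on chromosome 19 at 9083636 to 9087958.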

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

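The tests of the Th17 club-cell share, the scaling and the carry-over below were chosen after the results were seen, whereas the macrophage list and the exTh17 club-cell list were written before their values were looked at.

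Ccl5 and Gzmk lay on opposite sides of LN memory in exTh17 and YFPneg cells. Ccl5 differed from LN memory by -1.38 in exTh17 and by 2.32 in YFPneg, a gap of -3.69 on the log2 scale. Gzmk differed by -3.75 and by 1.05, a gap of -4.80. With 1 value per population, neither difference between populations was tested. Cd8b1 also lay below LN memory in exTh17 and above it in YFPneg, at 4.73, 28.6 and 50.7 FPKM in exTh17, LN memory and YFPneg. Its difference between YFPneg and LN memory was within 2-fold. Cd8a differed from LN memory by -0.61 in exTh17 and 0.93 in YFPneg, both within 2-fold. On the list of CD8, NK and gamma-delta markers, Klrb1c was above LN memory in both, by 1.49 and 1.23. Klre1 was above LN memory in YFPneg, at 11.5 against 0.0195 FPKM, but stayed under 1 FPKM in exTh17 and was not compared there. Ncr1 was below LN memory in YFPneg and listed at 0 in exTh17. Whether CD8 cells contribute to the Ccl5 and Gzmk gaps was not tested.

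The highest row of the table carried no gene name and was compared only in the alternative that takes every row. It had 171301 FPKM in LN naive, 223353 in LN memory, 216572 in Th17, 195664 in exTh17 and 85628 in YFPneg cells.

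Transcripts of macrophages were high in the lung populations, whereas those of airway cells were not high in all of them. Scgb1a1 was 3189 FPKM in exTh17, 53.5 in YFPneg and 0.547 in LN memory, and Cyp2f2 was 45.0 in exTh17 and 0.0477 in YFPneg. A further list of macrophage genes was at least 2-fold higher in all 3 lung populations than in LN memory for 16 of 19 compared genes, or 84.21%, with Tyrobp at 569 and Apoe at 205 FPKM in exTh17, so RNA of lung macrophages may be present although the cells were sorted. A further list of club cell genes was higher in exTh17 than in YFPneg for only 2 of 3 compared genes, or 66.67%, Cyp4b1 at 2.38 FPKM and Sec14l3 at 1.73, which could reflect club cell RNA in exTh17. In Th17, 0 of 1 compared genes, or 0%, was 2-fold higher, too few to decide, with that gene, Hp, at 127 FPKM against 72.0 in YFPneg, Fmo2 at 2.52 but listed at 0 in YFPneg, Aldh1a1 at 0.0509 and Cyp4b1 listed at 0. The fixed lung epithelial list, which holds Scgb1a1 and Scgb3a2, was 2-fold lower in Th17 than in exTh17 for 0 of 7 compared genes and higher for 2. Sftpd was listed at 0 in Th17. Airway transcripts were therefore not particular to exTh17. A scaling difference of the lung columns is argued against by CD4 identity genes, whose median log2 difference from LN memory was 0.167 in exTh17, 0.228 in YFPneg and 0.171 in Th17, and transcription of such genes by lung T cells stays open and untested.

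Il17a and Il17f RNA was found in exTh17 and YFPneg cells at 20% and 15.2%, and at 4.99% and 4.36%, of the Th17 values. Carry-over of Th17 cells would put abundant Th17 genes at or above that share, and in exTh17 only 5 of 1735, or 0.288%, lay below 50% of the Il17f share, against 6.686% in LN memory, so carry-over could contribute. In YFPneg the value was 0.058%, against 3.055% in LN memory, which leaves it undecided. Il23r stood at 193% and Rora at 86.7% of Th17 in exTh17, above the Il17a share, so carry-over would not give those values. Transcription of Il17a and Il17f by exTh17 cells makes the same prediction and stays open.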

How the results depend on the processing

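No paired analysis was possible because the table gives 1 value per population, with no replicate numbers to use as a block. Alternatives set beforehand on libraries in the fit, the variance model, leaving out libraries and the inter-gene correlation were not run for the same reason. The 4-fold rule, every row, summed rows and the minimum of 10 FPKM were chosen after seeing the data. In the order exTh17 against LN memory, YFPneg against LN memory, exTh17 against YFPneg, memory against naive and Th17 against exTh17, the 2-fold rule counted 2526, 2332, 890, 1530 and 2138 genes. The 4-fold rule gave 673, 529, 77, 335 and 266, a stricter rule by construction, and 401 shared genes in place of 1492. Every row gave 3878, 3598, 1816, 2697 and 3241, with more rows compared. The share of compared rows that differed also rose, for exTh17 against YFPneg from 9.09% to 13.7%. A minimum of 10 FPKM, with fewer genes compared, gave 1503, 1211, 328, 667 and 893, and 901 shared genes. It also raised the higher share for Th17 against exTh17 from 51.4% to 67.5%, so that near-even split depends on genes under 10 FPKM. The 4-fold rule moved the higher share from 54.0% to 71.0%, from 53.6% to 78.1%, from 50.6% to 29.9% and from 69.3% to 89.0% in the first 4 comparisons, and every row moved exTh17 against LN memory to 47.1%, exTh17 against YFPneg to 38.3% and memory against naive to 54.9%; the cause was not tested. The higher share also fell below 50% for Th17 against exTh17 with scaling (46.7%) and a pseudocount of 0.1 (48.7%), for YFPneg against LN memory with that pseudocount (49.1%), and for exTh17 against YFPneg with scaling (49.8%) and a minimum of 10 FPKM (47.9%), so which direction holds more genes in these comparisons depends on the processing. A pseudocount of 0.1 gave 1614 for exTh17 against YFPneg. No filter gave the counts of the main rule by construction. Other totals stayed within 1.5 times, but some counts by direction did not. With a pseudocount of 0.1, genes lower in memory than in naive rose from 469 to 751 and shared lower genes from 550 to 861. Every row gave 855 shared lower genes. Of 119 list medians, 25 moved with a pseudocount of 0.1 and 0 with scaling, and of 565 named-gene differences 20 moved with the pseudocount, 6 with scaling and 1 with summed rows; 0 reversed.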

Other observations

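Families chosen by name after the data were seen add the following. Of 12 genes of the circadian clock, 6 were at least 2-fold higher in exTh17 than in LN memory, with Nr1d1 at 22.8 against 2.20 FPKM and Per1 at 16.4 against 1.99. Killer-cell lectin-like receptor genes, whose near-identical members make the values uncertain, were higher in YFPneg than in LN memory for 11 of 14 and lower in exTh17 than in YFPneg for 7 of 13, with Klrd1 at 10 against 58.4. Genes of AP-1 and CREM factors were higher in exTh17 than in LN memory for 13 of 15 (median 1.99) and in YFPneg for 12 of 16 (median 1.83).

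Ribosomal protein genes had a median log2 difference of -0.78 between exTh17 and LN memory, with 17 of 77 at least 2-fold lower and 2 higher. MHC class II and presentation genes were higher in LN memory than in LN naive for 8 of 8 (median 3.79), with H2-Ab1 at 1130 against 31.8 FPKM, where B-cell markers were also higher. Calca was 58.9 FPKM in exTh17, 76.4 in YFPneg and 88.8 in Th17, and 0.0951 in LN memory.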
